A study of Homo sapiens with 2 samples.

How the data were processed

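Total RNA was measured in 2 samples, 1 from HARA, a human squamous cell lung cancer line, and 1 from HARA-B4, its subline that metastasises strongly to bone. Per the labels, both lines grew in the same medium with serum, and biotin-labelled cRNA was hybridised to 1 Affymetrix array for each line. No replicates were made, so each group holds 1 array (n = 1) and the number of arrays limits the precision of every value.

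The deposited values are linear probe set intensities (signals), 1 for each of 54675 probe sets on each array. Affymetrix Expression Console was used, per the submitters' processing notes, and its version, summary algorithm, background correction, scaling target and detection calls are not given in the sources used here. The values are all positive, from near 0 to 12368 in HARA and 11558 in HARA-B4. The mean signal after removal of the outer 2% was 115.6 in HARA and 116.0 in HARA-B4, so the arrays had been brought to about the same level before deposit. They were used as deposited, on the log2 scale, with no further scaling, and differences are HARA-B4 minus HARA.

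Genes were named from the platform annotation table. Of the probe sets, 41097 had 1 gene symbol, 1801 had several and 11777 had none. Only those with 1 symbol were named, and 41043 of them were matched by Entrez ID to the RefSeq gene table of assembly GRCh38.p14, giving 19741 genes. Some genes of the fixed panel and lists had no probe set named in the table and are not analysed here. No genomic coordinates are given, since the build behind the probe design is not given in the sources used here, and the RefSeq table served only for symbols and for which genes neighbour each other. XIST and Y-linked genes were left out.

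A background level was set at the 95th percentile, over both arrays, of the 162 probe sets of olfactory, taste and vomeronasal receptor genes, which a lung cancer line is taken not to use. It was 4.76 on the log2 scale, a signal of 27.2. Each gene took its probe set with the highest mean log2 signal. A gene above background on both arrays was counted when its log2 difference was at least 1 in size (2-fold). For a gene above background on 1 array only, the value on the other array was set to the background level, so its fold is a lower bound, and it was counted when that bound was at least 2-fold. With 1 array per group there are no residual degrees of freedom, so no p-value is given. The only repeat measurement is that of several probe sets of 1 gene on the same array, which is technical and says nothing of biological repeats.

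There were 38 gene lists fixed from general knowledge. For each list with at least 5 members above background on at least 1 array, the median log2 difference was placed among the medians of 10000 random lists of the same size, matched on mean level in 20 bins. Lists at or under the 2.5th or at or over the 97.5th percentile are called apart from random lists. The percentiles treat genes as independent and describe these 2 arrays only. For neighbouring genes, a running median of the log2 difference was taken over 25 successive genes above background on both arrays, within a chromosome, and compared with the highest and lowest running medians of 1000 shuffles of gene order.

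Named genes followed a rule. It took the 10 largest higher and 10 largest lower genes among those above background on both arrays whose probe sets above background all differed in the same direction. It also took the 5 brightest genes above background on 1 array only, for each array, with no probe set above background on the other. A fixed panel was added whatever its values, of which CCN2, IL11, CXCR4, MMP1, SPP1, JAG1, CXCL8, CDH1, VIM and KRT5 are given. In each list the rule took up to 4 members with the largest difference of at least 2-fold, or the 2 brightest members where none reached it. Genes named outside this rule are said to be chosen after their values were seen. The grouping, the background rule, the lists, the naming rule and all alternatives not said to be later were chosen before the data were examined.

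The alternatives were subtraction of the median difference, quantile normalization, removal of a trend with level (lowess), other background levels, the mean of all probe sets, removal of probe sets ending in _x_at or _s_at (which match several transcripts or genes), log2(signal + 16), folds of 1.5 and 3, agreement of all probe sets, means in place of medians, lists without shared genes, and windows of 15 and 51 genes. Alternatives chosen after seeing the data left out genes in shifted runs of neighbours or the HLA genes, and for the neighbouring genes removed the trend or removed shared probe sets and gene families.

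The scripts were tested on simulated data built from the HARA array with noise of the within-gene spread and 200 changed genes among 19741. The changed genes were drawn only from genes far above background in HARA, and the noise was equally large at all levels. The shares recovered therefore apply to bright genes and may not hold for dim ones. The 2-fold rule recovered 10% of 50 genes changed 1.5-fold, 58% of 50 changed 2-fold, 98% of 50 changed 3-fold and 100% of 50 changed 4-fold, and it called 0.0668% of 10486 unchanged genes. Of random lists drawn from 11479 genes, 4% were called apart. A block of shifted neighbours placed among 10192 shuffled genes gave 35 windows past the limits, all of them overlapping the block, and 0 windows passed without it. This simulation holds technical noise only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.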

Results

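Gene expression was measured in HARA, an established human squamous cell lung cancer line, and in HARA-B4, its highly bone-metastatic subline, with 1 Affymetrix array for each. The comparison asks how the transcripts of the bone-seeking subline differ from those of the parental line. In HARA 10888 genes were above background and in HARA-B4 10788, and 10197 were above background on both arrays. There were no replicates, so the values below are sizes of difference between 2 arrays with no p-value and no estimate of biological spread.

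Both arrays gave similar overall levels. The median probe set signal was 17.3 in HARA and 16.2 in HARA-B4, and 42.0% and 40.8% of probe sets were above background. The 3' to 5' signal ratio of ACTB was 1.39 in HARA and 1.31 in HARA-B4, and that of GAPDH was 0.986 and 1.01. The 8 hybridisation spike-ins differed by -0.09 to 0.19 on the log2 scale, and 12 poly-A spike-ins by -0.08 to 0.52. Log2 signals of probe sets above background on both arrays had a Pearson r of 0.957 across probe sets, which are not independent replicates. The gene differences had a median of 0.02 and an SD of 0.55, and the middle of the distribution, from the 25th to the 75th percentile, ran from -0.27 to 0.28.

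HARA-B4 differed from HARA by at least 2-fold in 683 genes above background on both arrays (6.70%), of which 319 were higher and 364 lower in HARA-B4. A further 97 genes were above background in HARA-B4 only and 119 in HARA only, with a bound of at least 2-fold. Differences of 4-fold or more were found for 45 higher and 39 lower genes. The largest higher values included IFI27, an interferon-induced gene, at a signal of 55.9 in HARA and 1066 in HARA-B4 (log2 difference 4.25), and COL4A1, a collagen chain of basement membranes, at 63.7 and 605 (3.25). The others on that side were IFIH1, a cytosolic sensor of viral RNA (5.11), MYADM (3.27), the calmodulin-like CALML3 of squamous epithelium (3.13), CD70, the ligand of CD27 (3.10), MTSS1 (signal 134 in HARA and 1075 in HARA-B4), the gelatinase MMP2 (2.98), the neutral amino acid transporter SLC1A4 (2.93) and VAV3 (2.81). A second probe set of IFIH1 differed by only 0.23, so the size of its difference depends on the probe set. HARA signals of IFIH1 (30.8), MYADM (32.3), CD70 (29.1) and VAV3 (35.3) lay close to the background level of 27.2, so the sizes of these differences are uncertain.

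Among genes above background on both arrays, the lowest value belonged to the protease inhibitor SPINK13, at a signal of 1080 in HARA and 50.5 in HARA-B4 (log2 difference -4.42). BCAT1, the cytosolic branched-chain amino acid transaminase, followed at 2471 and 138 (-4.17). CXCL8, the neutrophil chemokine interleukin-8, stood at 654 and 63.4 (-3.37). Lower values were also found for podocalyxin (PODXL, -3.22), the imprinted gene MEST (-3.13), the homeobox gene HOXB7 (-3.08), DSEL (-3.02), the desmosomal plakophilin PKP2 (-2.89), phospholipase PLCB1 (-2.85) and bleomycin hydrolase BLMH (-2.72). PLCB1 was close to background in HARA-B4, at a signal of 28.3.

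Several bright genes were above background on 1 array only. Their folds between the lines are lower bounds. In HARA-B4 only, TMPRSS15, the intestinal protease enteropeptidase, was at least 26.4-fold higher than in HARA, and TM4SF1, a membrane protein of the transmembrane 4 family, at least 21.2-fold. UTS2B was at least 13.4-fold higher, LOXL4, a lysyl oxidase-like enzyme, at least 12.02-fold and the myosin light chain kinase MYLK at least 10.5-fold. In HARA only, the adhesion-associated protein TRIP6 was at least 58.3-fold higher than in HARA-B4, HTATIP2 at least 50.2-fold and the calcium-binding protein CALB1 at least 46.1-fold. The mitochondrial glycerol-3-phosphate dehydrogenase GPD2 was at least 32.0-fold higher there and the ephrin receptor EPHA3 at least 25.3-fold.

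**Figure D1:**
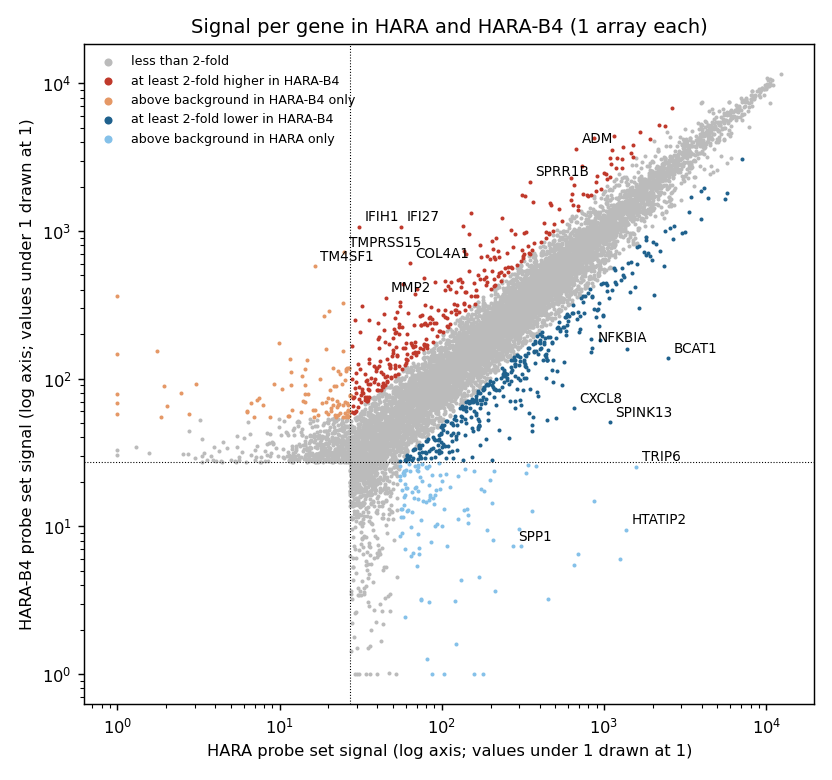
Probe set signal of each gene in HARA (horizontal, log axis) and HARA-B4 (vertical, log axis), 1 point per gene above background on at least 1 array, with dotted lines at the background signal of 27.2 and colours for at least 2-fold differences and lower bounds. Most points lie along the diagonal, with 319 genes higher and 364 lower in HARA-B4, and IFI27, BCAT1 and TRIP6 are among the points far from it.

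Probe sets of the same gene gave a technical check on these differences. In 4823 genes with several probe sets above background on both arrays, the within-gene SD of the log2 difference was 0.30. Of 269 such genes at 2-fold, the second probe set had the same sign in 256 (95.2%) and was itself at 2-fold in 154 (57.2%). The share at 2-fold was 8.30% in the dimmer genes and 5.10% in the brighter ones. A requirement that all of 2 or more probe sets pass left 64 higher and 68 lower genes. Among the named genes called at 2-fold on both arrays, IFIH1 and these others had a probe set under 2-fold: SAMD9 (0.52), PCDH7 (0.57), BMP2 (0.75), THBS1 (0.82), ETV5 (-0.33), VEGFA (-0.62) and PHLDA1 (-0.88).

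Genes tied to bone and to bone metastasis went both ways. Of 17 secreted regulators of osteoclasts and bone turnover above background, 5 were at least 2-fold higher in HARA-B4, 5 lower and 7 neither. The lower ones included CXCL8 and VEGFA, the vascular growth factor (-2.56, and -0.62 by another probe set), and the higher ones BMP7, a bone morphogenetic protein (1.91), and EDN1, the precursor of endothelin-1 (at least 3.26-fold on its main probe set, with another probe set above background in HARA). The list's median was -0.24, at percentile 3.12 of random lists and not apart from them. Among 11 genes known from bone metastasis models, 2 were higher and 3 lower, with a median of -0.14 (percentile 18.5). IL11, a cytokine of that group, was at background in HARA and at least 3.15-fold higher in HARA-B4. Osteopontin (SPP1) was at background in HARA-B4 and at least 10.1-fold lower, the protease ADAMTS1 at least 3.89-fold lower, and the activin antagonist FST had a difference of -1.63. CXCR4 differed by 0.15, JAG1 by -0.37, and CCN2 and MMP1 were at background on both arrays. Of 6 osteoblast and bone matrix genes, 1 was higher, BMP2 (1.10), and 1 lower, SPP1, with a median of -0.05 (percentile 45.4).

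TGF-beta response genes and matrix genes stood higher in HARA-B4. Of 24 TGF-beta response genes, 8 were at least 2-fold higher and 0 lower, with a median of 0.35 (percentile 99.94). COL4A1 and COL4A2, which form 1 collagen heterotrimer and share a promoter, differed by 3.25 and 2.51, the matricellular protein THBS1 by 1.99, and the ligand TGFB2 was at least 5.63-fold higher. Of 25 matrix and basement membrane genes, 6 were higher and 2 lower, with a median of 0.63 (percentile 100), and the laminin chain LAMB1 was among the lower ones (-2.35). That median rested on members shared with other lists: without them it was -0.33 in 17 genes, at percentile 1.08. It was also not apart with the background raised by 1 on the log2 scale, at 0.10 (percentile 83.5). Matrix proteases and their inhibitors were mixed, with 2 of 19 higher, 3 lower and a median of 0.03 (percentile 59.4). In that list MMP2 was higher, while ADAMTS1, MMP28 (at least 2.92-fold) and the inhibitor TIMP1 (-1.31) were lower. Of 20 integrin and adhesion genes, protocadherin PCDH7 was higher (1.88) and N-cadherin (CDH2) at least 3.95-fold lower, with a median of 0.14 (percentile 92.4). Of the fibroblast markers, FAP was at least 5.69-fold higher along with these groups and THY1 lower, and the list, which also holds MMP2, had a median of 0.36 (percentile 93.2). COL1A2, COL3A1, DCN and LUM, abundant fibroblast transcripts picked from that list after their values were seen, were at background on both arrays. COL1A1, another collagen gene, was above background on both.

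Basal squamous genes and squamous differentiation genes stood higher in HARA-B4 as groups. Of 20 basal squamous genes, 3 were at least 2-fold higher in HARA-B4 and 0 lower, with a median of 0.33 (percentile 99.98): KRT15 (1.997), the plakophilin PKP1 (1.82) and KRT16 (1.16). KRT5, a basal keratin, had a signal of 4723 in HARA and 4504 in HARA-B4. In the list of squamous differentiation and the cornified envelope, 7 of 17 genes were higher and 1 lower, with a median of 0.98 (percentile 100). SPRR1B, a cornified envelope precursor, was at 349 in HARA and 2154 in HARA-B4 (2.63), SPRR1A differed by 1.92, KRT1 was at least 4.91-fold higher, and the kallikrein KLK10 was lower (-1.88).

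Markers of an epithelial to mesenchymal shift were not apart from random lists as groups. Of 21 epithelial genes, 1 was higher and 3 lower, with a median of -0.01 (percentile 34.1), and of 15 mesenchymal genes, 1 was higher and 4 lower, with a median of -0.02 (percentile 44.1). E-cadherin (CDH1) differed by 0.23 and vimentin (VIM) by 0.29. Single members differed more: the simple-epithelium keratin KRT19 was at least 5.84-fold lower, the tight junction proteins CLDN1 (-2.46) and CLDN7 (at least 2.16-fold) were lower and CLDN4 at least 3.28-fold higher. In the mesenchymal list MMP2 was the higher gene (2.98), while CDH2 (at least 3.95-fold), smooth muscle actin ACTA2 (-1.37) and THY1 (at least 2.35-fold) were among the lower ones.

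Interferon-stimulated genes stood higher in HARA-B4, with 9 of 30 at least 2-fold higher, 0 lower and a median of 0.38 (percentile 100). Beside IFI27, the values were 1.84 for OASL, 1.83 for SAMD9, of which another probe set differed by 0.52, and at least 4.14-fold for IFIT2, of which another probe set differed by 0.47. Not every member followed: 6 of the 30 had negative differences. Of 15 genes of antigen processing and presentation, 6 were higher and 0 lower, with a median of 0.85 (percentile 100). They included NLRC5, the transactivator of MHC class I genes (at least 4.28-fold), the immunoproteasome subunits PSMB9 (1.86) and PSMB8 (1.46), and HLA-G (1.27). The HLA genes were measured almost wholly by probe sets ending in _x_at or _s_at, which match several transcripts or genes. Removal of such probe sets also took out members that are not HLA genes, such as PSMB8. The list's median without them was 0.082 in 9 genes (percentile 78.0). Without the HLA genes alone that median was 0.33 in 10 genes (percentile 99.13).

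The lists of NF-kappaB targets, of EGFR and MAPK output and of p53 targets stood lower in HARA-B4. Of 13 NF-kappaB targets, 3 were at least 2-fold lower and 0 higher, with a median of -0.32 (percentile 1.36), namely CXCL8, CXCL1 (at least 6.42-fold) and NFKBIA, which encodes the inhibitor IkappaB-alpha (-2.39). That list was no longer apart under 3 of 12 alternatives. Chemokines and cytokines as a wider list went both ways, 2 of 11 higher and 3 lower (median -0.05, percentile 38.5), and CXCL14 was among the higher ones (2.71). Of 27 genes of the EGFR family, its ligands and MAPK output, 7 were lower and 0 higher, with a median of -0.41 (percentile 0.01). The ligand EREG was at least 7.84-fold lower, and the feedback phosphatase DUSP4 (-2.09), the ETS factor ETV5 (-1.48) and PHLDA1 (-1.25) were lower. Of 19 p53 target genes, 3 were lower and 1 higher, with a median of -0.45 (percentile 0.02). GDF15 (-1.36), TP53I3 (-1.17) and XPC (-1.10) were lower, while CDKN1A, the cyclin-dependent kinase inhibitor p21, was higher (1.66). GDF15 was close to background in HARA-B4, at a signal of 29.0. Without probe sets ending in _x_at or _s_at 12 genes were left and the p53 median was -0.086 (percentile 28.7).

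Metabolic and stress lists showed smaller shifts. Of 29 NRF2 target genes, 2 were higher and 2 lower, with a median of 0.22 (percentile 99.4), the members being CBR3 (1.93), AKR1C3 (1.09), ALDH3A1 (-1.67) and GPX2 (-1.06), and the list was no longer apart with the mean of all probe sets. Of 21 cholesterol and fatty acid synthesis genes, 2 were higher, HMGCS1 (1.37) and SC5D (1.17), and 1 lower, the sterol sensor INSIG1 (-1.29), with a median of 0.25 (percentile 99.3) that was no longer apart under 3 of 12 alternatives. Of 29 hypoxia and glycolysis genes, 3 were higher and 2 lower, with a median of 0.06 (percentile 66.2), and these parted: adrenomedullin (ADM) was at 676 in HARA and 3596 in HARA-B4 (2.41) and PDK1 higher (1.31), while VEGFA and STC1 (at least 3.53-fold) were lower. Of 17 genes of xenobiotic metabolism, CYP2S1 (1.84), AHRR (1.36) and CYP1B1 (1.04) were higher and ALDH3A1 lower, with a median of -0.18 (percentile 6.85). CYP2S1 was close to background in HARA, at a signal of 27.9. Among 23 genes of the unfolded protein response only TRIB3 reached 2-fold (-1.02), with a median of -0.12 (percentile 3.74). Of 27 respiratory chain genes only SDHA did (1.27), with a median of -0.01 (percentile 14.6).

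Genes of the mitotic cell cycle list hardly differed. Of 39 mitotic cell cycle genes 0 reached 2-fold in either direction, with a median of 0.06 (percentile 58.9). The brightest, PCNA and RRM2, differed by -0.17 and 0.34. The same held for 24 ribosomal protein genes (median -0.03, percentile 8.15; RPL7 -0.05, RPL8 0.01) and 12 heat shock proteins (median 0.00, percentile 33.1; HSPD1 -0.02, HSP90AA1 -0.08).

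Developmental pathways and other lists gave few members at 2-fold. Of 13 Notch pathway genes, 3 were higher, HES4 (at least 2.94-fold), LFNG (1.39) and DLL1 (1.04), with a median of 0.17 (percentile 87.4). Of 13 Wnt pathway genes, WNT5A (1.47) and FZD7 (1.21) were higher, with a median of 0.03 (percentile 55.9). BMP7 and BMP2 were the 2 higher genes among 11 of the hedgehog and BMP pathways (median 0.12, percentile 73.4). Of 21 chromatin regulators, TET1 (1.20) was higher and EZH2 (-1.05) lower (median -0.07, percentile 19.9). Of 23 genes of cortical actin and motility, CDC42EP3 (1.25) and RHOC (1.03) were higher (median 0.17, percentile 95.2). Of 8 cancer-testis antigens, 3 were lower, MAGEA11 (at least 16.6-fold), MAGEA1 (-2.33) and PRAME (-1.43), with a median of -0.35 (percentile 2.26) that was no longer apart under 4 of 12 alternatives.

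Markers of other cell types gave no coherent difference. In blood and bone marrow markers 4 were above background and 0 reached 2-fold, with CD79A at -0.20 and HBB at -0.07. Of 4 osteoclast markers 1 was lower, carbonic anhydrase CA2 (-2.02). Of 2 endothelial markers, PECAM1 differed by -0.01, and FLT1 was just above background in HARA only, at signals of 27.7 and 20.5. The 4 neuroendocrine markers, with UCHL1 at 0.23 and SCG2 at -0.47, did not reach 2-fold. Of 6 alveolar and glandular lung markers 0 reached it (median 0.05, percentile 62.8; KRT7 -0.10, NKX2-1 -0.48). Of 6 fibroblast markers, MMP2 and FAP were higher and THY1 lower. Of the 34 lists with a median, 12 were apart from random lists, 8 high and 4 low, where 1.7 would be expected for lists of independent genes. Genes of a list can vary together and some lists share members, so 1.7 is no chance rate for a difference between the lines.

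**Figure D2:**
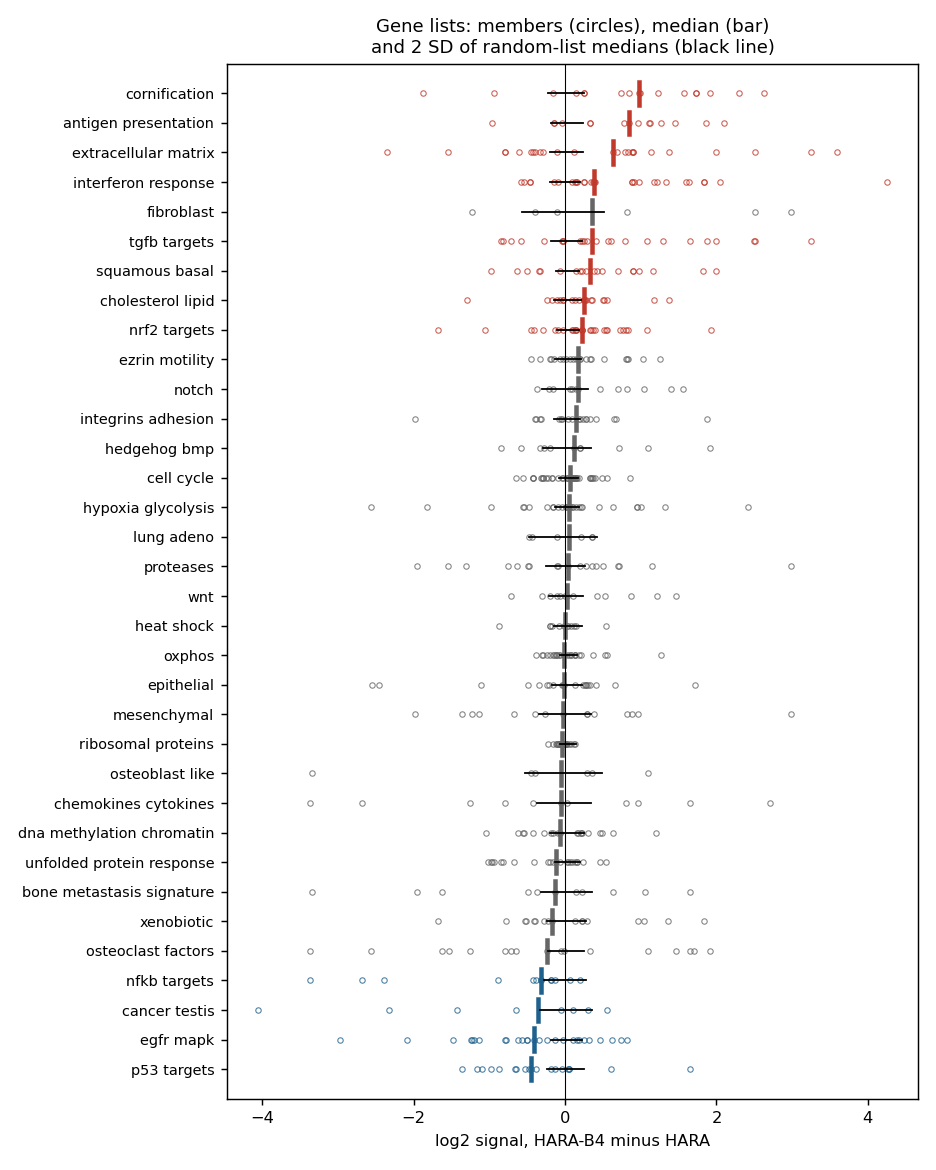
Log2 signal difference (HARA-B4 minus HARA, horizontal) of the members of each gene list (circles), with the list's median as a vertical bar, in red or blue where it was apart from random lists, and a black line of 2 SD on either side of the centre of the random-list medians. Cornification (0.98) and antigen presentation (0.85) have the highest medians and p53 targets (-0.45) and EGFR and MAPK output (-0.41) the lowest.

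Neighbouring genes shifted together in parts of the genome. Among 10192 genes in RefSeq order (GRCh38.p14), the running median of 25 neighbours passed the upper shuffled limit of 0.46 in 194 windows and the lower limit of -0.48 in 377, of 9628. These windows formed 19 runs, 10 higher and 9 lower in HARA-B4, which held 1087 genes (10.7%). Runs were joined only where they overlapped, so runs close together may be parts of 1 region and 19 is not a count of separate regions. The lowest run stretched from PSME1 to MNAT1 and held 111 genes, of which 53 were at least 2-fold lower, with a median of -0.96 and a lowest running median of -1.27. NFKBIA and NKX2-1 lie in it. A second lower run of 141 genes from BCAP29 to LINC00689 had a median of -0.61, with MEST, PODXL, LAMB1, EZH2 and INSIG1 among its genes. The highest running medians were 0.97 in the run of 58 genes from CCDC127 to RICTOR, which holds SDHA and AHRR, and 0.93 in the run of 79 genes from DBT to LINC00623, which holds VAV3 and RHOC. Over all their genes the medians of these runs were 0.52 and 0.59. In the run from CCDC127 to RICTOR only 37 of 58 genes (63.8%) were higher, the lowest share of any run. BMP7 lies in a higher run from RNF114 to OSBPL2, KRT15 and KRT16 in a higher run from CDK12 to NKIRAS2, and PLCB1, JAG1, PCNA and also the higher gene BMP2 in a lower run from DNAAF9 to ZNF133. The lower runs held 5.91% of the genes above background on both arrays and 128 of the 364 genes at least 2-fold lower (35.2%), and the higher runs 4.75% of the genes and 71 of the 319 higher ones (22.3%), an excess that follows in part from choosing the runs by the same differences.

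**Figure D3:**
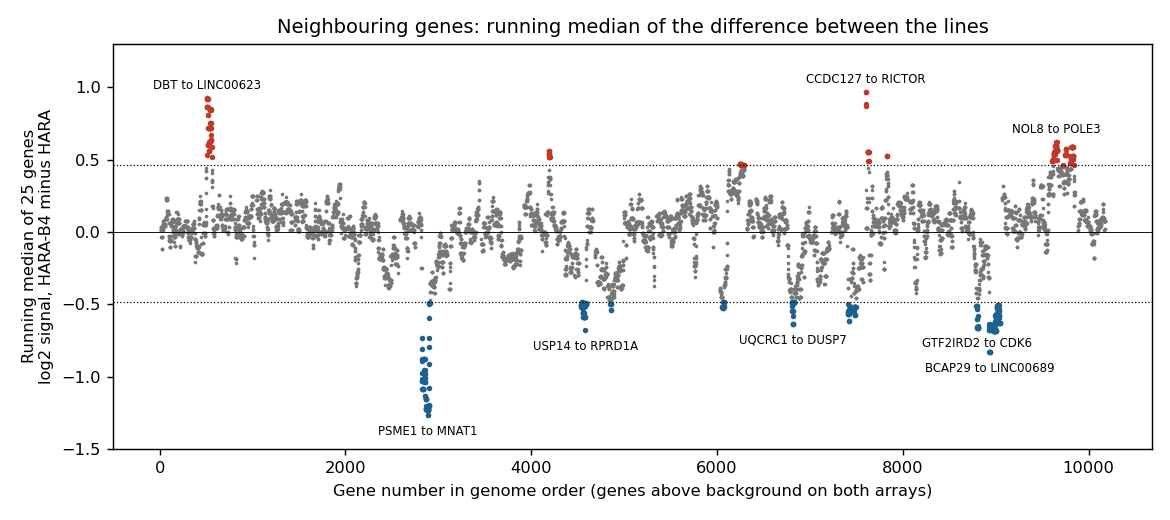
Running median over 25 neighbouring genes of the log2 signal difference (HARA-B4 minus HARA, vertical) by gene number in genome order (horizontal), with dotted lines at the limits from shuffled gene order and coloured points past them. The run from PSME1 to MNAT1 reaches -1.27, while that from CCDC127 to RICTOR reaches 0.97.

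**Figure D4:**
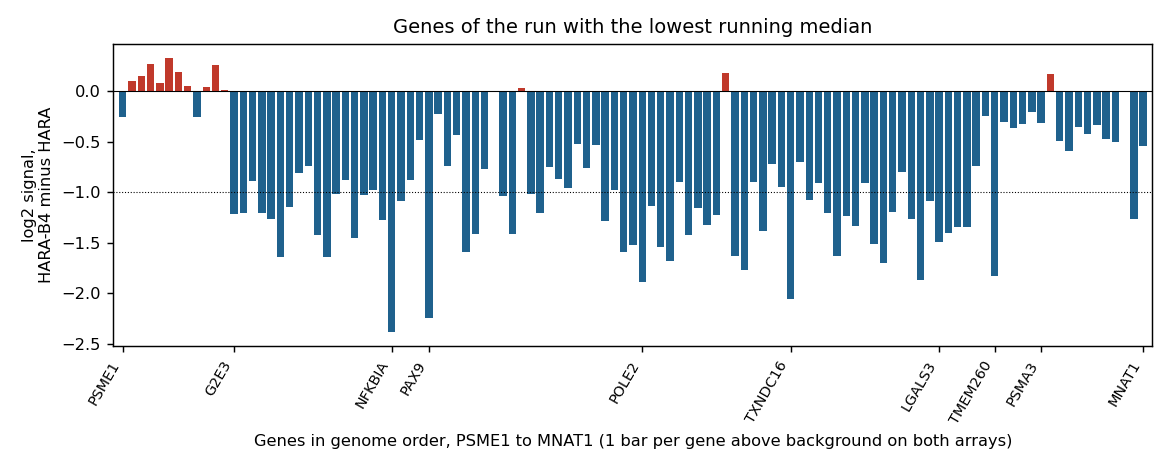
Log2 signal difference (HARA-B4 minus HARA, vertical) of each gene of the run from PSME1 to MNAT1 in genome order, 1 bar per gene above background on both arrays, with a dotted line at 2-fold lower. Of the 111 genes, 97 have negative differences.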

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

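Alternatives that left out genes in shifted runs, HLA genes, gene families or the trend among neighbours were chosen after seeing the data, and the cause of the moves below was not tested unless stated. Of 207 values under alternatives, 154 stayed within their limits (1.5 times for counts, 1 SD of random lists for medians), 52 moved and 1 reversed. The 3 scalings moved none of the 2-fold counts past 1.5 times, though quantile normalization gave 352 higher and 345 lower genes and so turned which was larger. Under each of the 3 scalings 12 lists were apart, and over all alternatives 10 to 15. No paired analysis was possible because each group holds 1 array. Signal over background limits dim genes: higher and lower counts were 560 and 601 with the 75th percentile of receptors as background (178 and 274 on 1 array only, HARA-B4 and HARA) and 2271 and 2544 with none. By construction they were 975 and 1039 at 1.5-fold, 105 and 94 at 3-fold and 64 and 68 where all of 2 or more probe sets passed, and 245 higher and 233 lower genes were left without shifted runs, so that the higher count was the larger one at 3-fold and without the runs too. Windows past the limits, higher and lower, were 82 and 146 with 15 genes, 404 and 879 with 51, and 127 and 244 without shared probe sets and families. List medians moved as follows. With the 75th percentile background, antigen presentation was 0.33, cancer-testis -0.61 and matrix 0.40, and with no background 0.38, -0.052 and 0.81. With the background raised, cancer-testis was -0.058, cornification 0.74, matrix 0.10 and NF-kappaB -0.63. With the mean of probe sets, antigen presentation was 0.97, cornification 0.74, EGFR and MAPK -0.31, matrix 0.19, interferon 0.60 and basal squamous 0.22. Without _x_at and _s_at probe sets, antigen presentation was 0.082, cancer-testis -0.65, matrix 0.81, interferon 0.51, NRF2 0.42, p53 -0.086 and TGF-beta 0.68. With log2(signal + 16), cornification was 0.84 and matrix 0.43. As means of members, antigen presentation was 0.73, cancer-testis -0.94, cornification 0.84, matrix 0.46, interferon 0.71, NF-kappaB -0.85 and TGF-beta 0.67. Antigen presentation without HLA genes was 0.33, and matrix without genes shared between lists reversed to -0.33. The TGF-beta, basal squamous, cornification, interferon and EGFR and MAPK lists were apart under all 12 alternatives. Subtraction of the median and removal of the trend could hardly change this, since they move a list and its level-matched random lists alike. Of 106 named genes at 2-fold, 0 reversed under the 9 alternatives run on them. As these genes were taken at 2-fold in the main analysis, a reversal was unlikely from the start. Those still at 2-fold were 74 of the 76 measured without _x_at and _s_at probe sets and 79 of the 98 with the mean of probe sets. They were 90 of 106 with the background raised, and at least 97 of 106 under the other 6.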

Other observations

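The histone and connexin groups and the tests on failed probe sets, blood, marrow or stromal cells, adjacent lost genes, HLA genes and DNA copy number were chosen only after the results were seen. Of 22 replication-dependent histone genes above background, 14 had signals at least 2-fold lower in HARA-B4 and 0 higher. All 22 had negative differences, with a median of -1.25. These are differences of array signal, and how fully the labelling captured histone transcripts was not tested. H1-2 differed by -2.13, H2AC6 by -2.03 and H2BC12, at a signal of 2363 in HARA, by -1.25. These genes share sequence, and without probe sets that match several transcripts 12 were left, 6 of them lower, with a median of -1.03. After subtraction of the median difference, removal of the trend and quantile normalization the medians were -1.27, -1.26 and -1.19. Of 9 other histone genes 0 reached 2-fold, with a median of -0.26.

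Among 8 connexin genes, which encode gap junction channels, 5 were at least 2-fold higher in HARA-B4 and 0 lower, with a median of 1.20. GJA1, at 1123 in HARA and 3526 in HARA-B4, differed by 1.65, GJB2 by 1.98 and GJB6 by 2.45, while GJB5 differed by -0.37. The count of 5 was the same under each of the 3 scaling alternatives. As groups picked for their values, they have no chance rate.

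In the first pattern weighed, 37 genes were bright in HARA and at or under background in HARA-B4 with a bound of at least 4-fold. Of 39 such genes picked by their brightest HARA probe set alone, 15 had a second probe set above background in HARA, and 14 of these were at least 2-fold lower by it (93.3%), which argues against single failed probe sets. The nearest neighbours of the 37 in HARA, 73 genes, had a median of -0.11 (25th to 75th percentile -0.53 to 0.10), which argues against a loss of DNA that reaches neighbours as the cause for most of them. Such a loss cannot be told apart for 2 of the 37, whose neighbour was also lost, nor failed probe sets for the 24 of the 39 genes with no second probe set above background. Silencing of single genes, or loss of DNA of 1 gene, may explain the genes seen by 2 probe sets and was not tested.

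The second pattern was the higher level of interferon and antigen presentation genes. Of 15 human blood and marrow markers 4 were above background and 0 at least 2-fold higher, so no rise in these markers was seen. The cutoff for this test was set after the values were seen, so it cannot exclude blood or marrow cells. Of stromal genes FAP and MMP2 were higher, and COL1A1 was at 185 in HARA and 140 in HARA-B4. COL1A2, COL3A1, DCN and LUM stayed under background in HARA-B4, with no probe set above a signal of 15.7. They were picked after their values were seen, so they cannot exclude human stromal cells. With the trend removed the interferon list's median was 0.41, against 0.38 before, which argues against a level-dependent difference between the arrays. Its percentile stayed at 100, which decides nothing, since the random lists were already matched on mean level. Whether shared signal raised the antigen presentation list stays open, since it lay at percentile 99.13 without HLA genes but at 78.0 without probe sets that match several transcripts or genes, and only 1 of the 16 HLA probe sets above background is not marked as shared (0.66). A state of standing interferon signalling in HARA-B4 could give this pattern, as could a difference between the 2 cultures on the day, and a single array per line cannot separate them.

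The third pattern was the shift of neighbouring genes. With shared probe sets and gene families thinned out 16 of the 19 runs again held a window past the limits, and with the trend removed 18 did, which argues against both as the whole cause. Gains and losses of DNA in HARA-B4 may explain the runs but cannot be told apart from other causes, because DNA is not analysed here. The median share of genes that differed in the run's direction, 83.8%, follows from how the runs were chosen and decides nothing. Within the lowest run, parted after the values were seen, the 83 genes from G2E3 to TMEM260 had a median of -1.19 with 81 negative, the 12 genes before them 0.09 with 2 negative, and the 16 after them -0.36 with 14 negative.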
